A study of Rattus norvegicus with 10 samples.

How the data were processed

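Each of the 10 samples gave 1 Affymetrix Rat Genome 230 2.0 array, hybridised with biotin-labelled RNA and read in 1 colour. The deposited values are linear signals, 1 per probe set (unit: intensity), which the authors summarised with GCOS 1.0 per the submitters' processing notes. The summary algorithm, the background step and the scaling target are not given in the sources used here, and detection calls were not used here. The mean signal of an array after leaving out 2% of the probe sets at each end differed from the mean over all arrays by at most 0.00340%, so the deposited scaling was kept. The table holds 31099 probe sets, of which 57 control probe sets were left out. Of the others, 20826 carry 1 gene symbol, 436 several and 9780 none. Symbols were brought up to date with the gene table of rat assembly GRCr8 for 20758 probe sets by gene number and 2 by transcript, and kept for 66, which gave 14217 distinct symbols. The assembly served for names and for the order of neighbouring genes only.

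Signals were taken to log2(signal + 5), where 5 is the 20th percentile of all values rounded to a whole number, so folds of dim genes are understated. Probe sets in the lowest 40% of mean log2 signal over all arrays were left out, 12417 in number, and 18625 probe sets of 10586 genes were tested. A gene present only in some tumours can fall under this filter: 1 and 2 of the left-out probe sets exceeded a signal of 100 in control replicates 1 and 2, 9 and 13 in tumours without metastasis and 14 and 64 in tumours with lung metastasis. Groups and replicates follow the labels. Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group, a contrast and eBayes with a variance trend, 2-sided), on the 6 kidneys for the comparisons among kidneys, on controls and tumours, on the 4 tumours, and on treated kidneys and tumours. Kidneys and tumours were not pooled for a comparison of one kind alone, because tumours vary more. The comparisons of tumours with kidneys used 1 spread per probe set for both kinds, so their p-values rest on unlike spreads. The tumour side was the mean of the group means with and without metastasis. P-values were adjusted by Benjamini-Hochberg over all probe sets tested, and a probe set passed at an adjusted p under 0.05. A gene was read from its probe set with the highest mean, and the ± after a log2 change is the standard error from limma.

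Gene lists (27 in number, 665 genes, 582 matched to a probe set) were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The lists covered cell types (proximal tubule, distal nephron and collecting duct, podocyte, endothelial, macrophage and pan-leukocyte, T and B cell, erythroid, adipocyte, adrenal cortex and lung epithelium markers) and processes (tubular injury, NRF2 and glutathione, iron handling, p53 targets, cell cycle, stroma and matrix, epithelial adhesion and keratins, mesenchymal and invasion, HIF and glycolysis, oxidative phosphorylation, fatty acid oxidation, Wnt targets, immediate early, heat shock and unfolded protein, interferon-responsive, amino acid and xenobiotic metabolism), beside single genes read in every comparison. Genes to name were the 8 with the largest rise and the 8 with the largest fall per comparison among those that passed, carry 1 symbol and had all arrays of one side apart from the other, the 3 members of each list with the smallest p, and the single genes. Where fewer than 5 passed in a direction, the 5 genes with the smallest unadjusted p stood in. The text prints part of these. The lists, the tests of the comparisons, the filter, the naming rule and the alternatives were chosen before the data were examined. Some tests of explanations were chosen after the results were seen and are named as such where they are given. Cdkn2a and Cdkn2b, and the genes of chromosome 4 given per tumour, were looked at after their values were seen.

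The fits were tested on simulated data with the spread of these arrays and 100 changed probe sets of each size. Of those changed by 1 and 2 log2 units, limma recovered 57 and 96 for 1 week against control, 69 and 98 for 3 weeks against control, 69 and 98 for 3 weeks against 1 week, 0 and 1 for tumours against control, 0 and 0 for metastasis, and 12 and 86 for tumours against treated kidney, with 8, 17, 16, 1, 0 and 2 false calls. With so few changed probe sets the adjusted threshold is stricter than where many change, so recovery in the real comparisons may be higher. The number of arrays, 2 per group, limits the precision. Alternatives were quantile normalization, median scaling, the pseudocount divided by 4 and times 4, no filter and a filter of the lowest 60%, all 10 arrays in the fit, eBayes without trend and with robust settings, an adjusted p under 0.10, at least 2-fold, probe sets averaged per gene, a block by replicate number for the kidneys, the 4 tumours as 1 group, and leaving out each array.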

Results

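RNA of 10 rat tissue samples was measured, each on 1 Affymetrix Rat Genome 230 2.0 array, in 5 groups of 2 arrays. The groups were untreated control kidney, kidney after 1 week of ferric nitrilotriacetate (Fe-NTA), kidney after 3 weeks of Fe-NTA, Fe-NTA-induced renal cell carcinoma without invasion of the peritoneum or metastasis, and carcinoma of rats with metastasis to the lung. Fe-NTA is an iron chelate that reaches the proximal tubule of the kidney, where its iron drives oxidative damage, and repeated doses lead to carcinoma. The tumours without metastasis were titled G1 (replicate 1, small nuclei) and G3 (replicate 2, enlarged nuclei), and those with lung metastasis G2 (replicate 1, regular-sized nuclei) and G3 (replicate 2, enlarged nuclei). The median signal of an array lay between 26.9 and 32.6. The median over probe sets of the SD within a group was 0.13 log2 in control kidneys, 0.17 after 1 week, 0.12 after 3 weeks, 0.30 in tumours without metastasis and 0.39 in tumours with it. The labels do not say that the arrays came from separate animals, so the p-values measure the spread between these arrays. The series' design text names Wistar rats and a cross of F344 and BN rats. The labels do not give the strain of an array, so tumours and kidneys may differ in strain. A probe set passed at an adjusted p under 0.05 in limma, and a gene list was called at an adjusted p under 0.05 in camera of limma.

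The first comparison asked which transcripts differed from control kidney after 1 week of Fe-NTA. Havcr1, which encodes the tubular injury molecule KIM-1, rose from a mean signal of 16.8 ± 7.18 to 1823 ± 519 (SD, n = 2 each). Its log2 change was 6.40 ± 0.26, adjusted p = 0.000226 in limma (± SE here and below). Cell cycle genes rose, such as the cyclin gene Ccna2 (2.81 ± 0.41). The spindle-associated Gtse1 (2.70 ± 0.20) and the tubulin gene Tubb6 (2.96 ± 0.18), on no list here, were among the largest rises. Cdkn1a (2.73 ± 0.32), which encodes the p53-induced cell cycle inhibitor p21, rose as well. Genes of the differentiated proximal tubule fell, such as the cytochrome P450 Cyp2e1 (-1.70 ± 0.15) and the organic anion transporter Slc22a6 (-1.34 ± 0.23). In total 322 probe sets rose and 91 fell of 18625 tested, at 263 and 51 genes.

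Of 38 measured cell cycle genes, 28 rose and 10 did not pass (35 rose adjusted over the list alone). Examples were the mitotic kinase Cdk1 (2.04 ± 0.19), the topoisomerase Top2a (1.95 ± 0.20) and the proliferation marker Mki67 (1.82 ± 0.18). Among 27 tubular injury markers 12 rose and 15 did not pass (21 rose and 1 fell adjusted over the list alone). These included the protease inhibitor Timp1 (2.11 ± 0.16), the hyaluronan receptor Cd44 (1.88 ± 0.18) and the fibrinogen chain Fgb (3.04 ± 0.37). Of 18 p53 targets 6 rose and 12 did not pass (7 rose adjusted over the list alone), with Plk2 (1.84 ± 0.17) and Phlda3 (1.69 ± 0.16) beside Cdkn1a. Of 16 immediate early genes, which are transcribed within minutes of a stimulus, 5 rose and 11 did not pass (8 rose adjusted over the list alone), for example Egr1 (1.88 ± 0.23) and Ccn1 (1.69 ± 0.25). In the Wnt target list 3 rose and 8 did not pass (3 rose adjusted over the list alone). Those that rose were Fosl1 (2.06 ± 0.24), Myc (1.84 ± 0.23) and Cd44, which also answer to growth factors. Camera gave adjusted p = 2.2e-29 for the cell cycle list, 3.1e-11 for tubular injury, 3.7e-05 for p53, 2.5e-06 for immediate early and 0.0250 for Wnt. With an estimated correlation these were adjusted p = 0.184, 0.184, 0.105, 0.105 and 0.184.

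Leukocyte and matrix genes were higher at this time. Of 27 macrophage and pan-leukocyte markers 8 rose and 19 did not pass (18 rose adjusted over the list alone). They included the actin-binding Coro1a (1.42 ± 0.13), the tetraspanin Cd53 (1.19 ± 0.14) and the growth factor receptor Csf1r (1.06 ± 0.17). Of 31 stroma and matrix genes 6 rose and 25 did not pass (15 rose adjusted over the list alone), among them the basement membrane collagens Col4a1 (0.93 ± 0.12) and Col4a2 (0.84 ± 0.14). In the mesenchymal and invasion list 2 rose and 25 did not pass (10 rose adjusted over the list alone). These were Spp1 (1.57 ± 0.20), which encodes osteopontin, and the intermediate filament gene Vim (1.17 ± 0.20). Of 23 interferon-responsive genes 2 rose and 21 did not pass (5 rose adjusted over the list alone), the immunoproteasome subunits Psmb8 (1.29 ± 0.22) and Psmb9 (1.25 ± 0.22). The adjusted p in camera was 4.2e-09 for the macrophage and pan-leukocyte list, 4.7e-08 for stroma and matrix, 0.00701 for mesenchymal and invasion and 0.000524 for interferon. They were adjusted p = 0.105, 0.207, 0.184 and 0.432 with an estimated correlation. The mean change of the interferon list was 0.81 in 1-week replicate 1 and 0.19 in replicate 2. Without replicate 1 its camera adjusted p was 0.150. The same array stood apart in 1 of 2 signs of RNA quality. Its Gapdh 3' minus 5' log2 difference was 0.70, against 0.20 to 0.29 in the other 5 kidneys. Its beta-actin 3' minus 5' difference, 0.98, lay within their range of 0.82 to 1.15.

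Lists of the tubule and of metabolism were lower, as were those of endothelial and heat shock genes. Of 31 proximal tubule markers 5 fell and 26 did not pass (17 fell adjusted over the list alone), with the water channel Aqp1 (-0.78 ± 0.13) as a further example. In the amino acid and xenobiotic metabolism list 2 fell and 28 did not pass (14 fell adjusted over the list alone). These were the acetyltransferase Nat8 (-1.52 ± 0.15) and the tryptophan pathway enzyme Haao (-1.33 ± 0.24). No fatty acid oxidation gene passed over all probe sets (5 fell adjusted over the list alone), and Acaa2 (-0.59 ± 0.15) is an example, which passed without 1-week replicate 2 (adjusted p = 0.0376 in limma). The list had a mean change of -0.34. No member passed among endothelial markers (mean -0.20), distal nephron and collecting duct markers (mean -0.14) and oxidative phosphorylation genes (mean -0.07), which were lower as sets. The oxidative phosphorylation mean was -0.18 in 1-week replicate 1 and 0.04 in replicate 2, which differ in sign. In the heat shock and unfolded protein list 1 fell and 17 did not pass, the transcription factor gene Xbp1 (-0.70 ± 0.13), and the set was lower. The set test camera gave adjusted p = 4.1e-13 for the proximal tubule list, 1.5e-11 for amino acid and xenobiotic, 3.1e-09 for fatty acid oxidation, 0.0144 for endothelial, 0.0199 for distal nephron, 0.00944 for oxidative phosphorylation and 0.0121 for heat shock. An estimated correlation gave adjusted p = 0.184, 0.222, 0.105, 0.184, 0.184, 0.709 and 0.264, in that order.

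Targets of the oxidant-responsive factor NRF2 went both ways, with 3 that rose, 1 that fell and 23 that did not pass. Srxn1 (1.49 ± 0.20) and Gpx2 (1.52 ± 0.19), which reduce peroxidised protein and peroxides, rose, and Osgin1 (-1.22 ± 0.16) fell. Hmox1, which encodes heme oxygenase 1, had a log2 change of 0.72 ± 0.21, adjusted p = 0.142 in limma. Camera did not call the lists of NRF2 (adjusted p = 0.744, median 0.05, mean 0.17), iron handling (0.279), HIF and glycolysis (0.939), epithelial adhesion (0.500), podocyte (0.744, median -0.01, mean 0.03), T and B cell (0.609) and adipocyte (0.0954) genes. Here and below, a median and mean are added where these and the directions of camera and fry differ in sign.

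The count of 413 probe sets became 24 and 40 without control replicate 1 or 2. It was 99 and 1385 without 1-week replicate 1 or 2, and 180 and 184 without 3-week replicate 1 or 2. It was 212 with dim probe sets kept, 172 without a variance trend and 883 at an adjusted p under 0.10. With the tumours added to the fit limma called 0, with 843 at an unadjusted p under 0.05, against 3301 without the tumours. Without 1-week replicate 2 there were 655 higher and 730 lower. Camera calls of the distal nephron and oxidative phosphorylation lists ended without control replicate 1 (adjusted p = 0.0808 for both) or 1-week replicate 1 (0.0560 and 0.785). The oxidative phosphorylation call also ended under quantile normalization (0.373), where its mean was -0.000876. With the lowest 60% left out the distal nephron (0.0607) and endothelial (0.270) calls ended. The Wnt call ended with dim probe sets kept (0.291), without control replicate 1 (0.0575) or without 1-week replicate 2 (0.0912). The endothelial call ended without control replicate 2 (0.0573) and the heat shock call without 1-week replicate 2 (0.191), where its mean was 0.0461.

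After 3 weeks of Fe-NTA more genes differed from control kidney, and losses of tubule genes stood beside the injury response. Havcr1 rose to a mean signal of 2999 ± 222 (SD, n = 2), a log2 change of 7.14 ± 0.26, adjusted p = 5.1e-05 in limma. Among the genes that rose most were Gpnmb (4.03 ± 0.26), a membrane protein of macrophages and injured tubules, Fgb (4.35 ± 0.37) and the cytokine gene Il24 (4.32 ± 0.39). The complement regulator Cfi (3.99 ± 0.54) and the phosphate transporter Slc34a2 (3.82 ± 0.14) rose too. Among the genes that fell most were Dhrs7l1 (-6.56 ± 0.33), the organic anion transporters Slco1a1 (-5.51 ± 0.59) and Slco1a6 (-3.86 ± 0.40) and the amino acid transporter Slc7a12 (-5.44 ± 0.28). The histamine-degrading Hnmt (-4.29 ± 0.20) and the deiodinase Dio1 (-3.75 ± 0.31) followed. Altogether 2286 probe sets rose and 1540 fell, at 1556 and 1041 genes.

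Proximal tubule markers fell broadly: of 31 measured, 24 fell and 7 did not pass (25 fell adjusted over the list alone). Examples were Slc22a6 (-3.24 ± 0.23) and Cyp2e1 (-2.37 ± 0.15) and the aminopeptidase Anpep (-1.76 ± 0.13). Of 30 amino acid and xenobiotic metabolism genes 28 fell and 2 did not pass (28 fell adjusted over the list alone). They included Nat8 (-3.58 ± 0.15), the choline pathway enzyme Dmgdh (-2.08 ± 0.16) and the tyrosine pathway enzyme Fah (-1.84 ± 0.15). In the fatty acid oxidation list 16 fell and 8 did not pass (20 fell adjusted over the list alone), with the peroxisomal Ehhadh (-2.52 ± 0.19) and the mitochondrial Acaa2 (-1.29 ± 0.15) and Hadh (-1.05 ± 0.12). Of 38 oxidative phosphorylation genes 10 fell and 28 did not pass (19 fell adjusted over the list alone), for example the complex II subunits Sdha (-0.59 ± 0.11) and Sdhd (-0.55 ± 0.11). Among 16 endothelial markers 2 fell and 14 did not pass (2 fell adjusted over the list alone), Vwf (-1.81 ± 0.38) and Emcn (-0.54 ± 0.14). In the distal nephron and collecting duct list 2 rose, 2 fell and 20 did not pass (2 rose and 2 fell adjusted over the list alone). Egf (-1.23 ± 0.21) and the proton pump subunit Atp6v1b1 (-1.11 ± 0.19) fell, and the prostaglandin receptor Ptger3 (1.17 ± 0.23) rose. Camera gave adjusted p = 3.7e-18 for the proximal tubule list, 3.1e-19 for amino acid and xenobiotic, 1.7e-12 for fatty acid oxidation, 8.9e-10 for oxidative phosphorylation, 0.00914 for endothelial and 0.0477 for distal nephron. Their values with an estimated correlation were adjusted p = 0.188, 0.188, 0.108, 0.342, 0.188 and 0.190. The distal nephron call ended under quantile normalization (adjusted p = 0.129) and median scaling (0.0541). It ended with dim probe sets kept (0.0527), the lowest 60% left out (0.173) or probe sets averaged per gene (0.0565). The endothelial call ended with the lowest 60% left out (0.0719). The distal nephron call also ended without control replicate 1 (0.0960) or 3-week replicate 2 (0.0984).

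Injury, leukocyte and matrix genes rose. Of 27 tubular injury markers 23 rose, 1 fell and 3 did not pass (23 rose and 2 fell adjusted over the list alone), including Timp1 (3.13 ± 0.16) and Cd44 (3.44 ± 0.18). Of 27 macrophage and pan-leukocyte markers 25 rose and 2 did not pass (26 rose adjusted over the list alone). Examples were C1qb (2.13 ± 0.14), a complement subunit made by macrophages, and Cd53 (2.24 ± 0.14) and Coro1a (1.85 ± 0.13). Among 10 T and B cell markers 7 rose and 3 did not pass (8 rose adjusted over the list alone), with the T cell receptor subunits Cd3g (2.08 ± 0.29) and Cd3e (1.56 ± 0.26) and the kinase Lck (1.21 ± 0.20). In the stroma and matrix list 25 rose and 6 did not pass (27 rose adjusted over the list alone), such as Loxl1 (1.82 ± 0.18), which cross-links elastin, and Col4a1 (1.27 ± 0.12). In the mesenchymal and invasion list 16 rose, 1 fell and 10 did not pass (16 rose and 2 fell adjusted over the list alone), with Vim (2.40 ± 0.20) and Spp1 (2.38 ± 0.20) and the chemokine receptor Cxcr4 (2.38 ± 0.24). Interferon-responsive genes followed, of which 12 rose and 11 did not pass (14 rose adjusted over the list alone), with Psmb8 (2.09 ± 0.22) and the transcription factor Irf1 (1.48 ± 0.22). The adjusted p in camera was 4.1e-11 for the tubular injury list, 1.4e-14 for macrophage and pan-leukocyte, 0.000642 for T and B cell, 4.5e-10 for stroma and matrix, 0.000210 for mesenchymal and invasion and 3.2e-05 for interferon. With an estimated correlation these were adjusted p = 0.188, 0.0680, 0.342, 0.188, 0.140 and 0.342. The interferon, matrix and T cell genes stood higher in the same arrays as the macrophage and pan-leukocyte markers, whose mean lay 1.53 and 1.58 log2 above control in replicates 1 and 2.

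Cell cycle genes stood above control at 3 weeks too, where 24 rose, 1 fell and 13 did not pass (29 rose and 1 fell adjusted over the list alone). The replication licensing genes Mcm4 (1.30 ± 0.19) and Mcm6 (1.10 ± 0.18) rose, while the mitotic kinase gene Melk (-1.17 ± 0.16) fell. Of 18 p53 targets 8 rose and 10 did not pass (8 rose adjusted over the list alone), among them the death receptor Fas (2.08 ± 0.25) and Phlda3 (2.00 ± 0.16). In the immediate early list 11 rose and 5 did not pass (12 rose adjusted over the list alone), with Egr1 (2.42 ± 0.23) and Egr2 (2.84 ± 0.21). In the Wnt target list 5 rose and 6 did not pass (5 rose adjusted over the list alone), with Myc (2.67 ± 0.23) and Fosl1 (2.11 ± 0.24). The set test camera gave adjusted p = 6.6e-07 for the cell cycle list, 0.0132 for p53, 5.9e-06 for immediate early and 0.0292 for Wnt. They were adjusted p = 0.377, 0.188, 0.114 and 0.190 with an estimated correlation. The Wnt call ended with dim probe sets kept (adjusted p = 0.209) or the lowest 60% left out (0.0545).

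In the NRF2 and glutathione list 5 rose, 8 fell and 14 did not pass. The glutathione synthesis enzyme Gclc (-1.80 ± 0.15), the NADPH-producing Me1 (-1.72 ± 0.14) and Osgin1 (-2.97 ± 0.16) fell, and Hmox1 rose by 1.03 ± 0.21. Of the iron handling genes 6 rose, 1 fell and 6 did not pass. The ferroxidase genes Cp (2.13 ± 0.25) and Heph (1.12 ± 0.15) rose, and Aco1 (-1.42 ± 0.18), which encodes the iron-regulatory protein IRP1, fell. The erythroid genes Alas2 (-2.73 ± 0.45) and Hbb (-2.43 ± 0.62) fell, and these are the 2 tested of that list, too few for a set test. Hbb had signals of 5152 and 3284 in control and 343 and 1672 in 3-week kidneys. Ptprz1, a receptor-type phosphatase gene, rose by 2.10 ± 0.31, and Met, the receptor of hepatocyte growth factor, by 0.82 ± 0.22. Mtap, an enzyme of methionine salvage, rose by 1.16 ± 0.18. Camera did not call the lists of NRF2 (adjusted p = 0.275, median 0.08, mean -0.00200), iron handling (0.192), epithelial adhesion (0.0518), podocyte (0.761, median 0.04, mean 0.04), adipocyte (0.0564), HIF and glycolysis (0.400, median 0.01, mean 0.04) and heat shock (0.269, median -0.04, mean 0.05) genes. The means of the HIF, NRF2, heat shock and podocyte lists changed sign under another scaling. In the epithelial adhesion list 7 rose, 1 fell and 11 did not pass, such as the tight junction gene Cldn7 (2.09 ± 0.14), and in the HIF and glycolysis list 2 rose, 5 fell and 19 did not pass.

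The count of 3826 became 1806 and 1941 without control replicate 1 or 2, and 1482 and 1781 without 3-week replicate 1 or 2. It was 102 (44 higher and 58 lower) with the tumours added to the fit and 1828 with at least a 2-fold change also required. The median log2 change of all tested probe sets was 0.10. Median scaling of the arrays moved it by -0.17, and the share of higher calls went from 59.7% to 38.0%.

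The changes after 1 and 3 weeks overlapped. Of the probe sets past the threshold at both times, 281 rose and 81 fell at both, and 0 changed in opposite directions. Independent lists of these sizes would share 39.5 and 7.52. Havcr1, Fgb, Cd44, Timp1, Phlda3, Nat8 and Slc22a6 are among the genes that passed in the same direction both times. Both comparisons use the same 2 control arrays, and 100 simulations of unchanged groups against those controls shared at most 1 probe set. Unchanged groups give few calls to share, so this does not measure how much of the overlap comes from the shared controls. The correlation of the log2 changes across probe sets, which are not independent replicates, was 0.692 against a simulated 0.499. The covariance was 0.194 against 0.0272, a difference of 0.167. Separate controls for each time would be 1 array each, and this was not tried, so part of the overlap may come from the shared ones. The 362 shared probe sets became 23 and 39 without control replicate 1 or 2 and 97 and 932 without 1-week replicate 1 or 2. Without 3-week replicate 1 or 2 they became 111 and 142. Without 1-week replicate 2, 17 probe sets changed in opposite directions, and 0 without any other array.

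The third comparison set 3 weeks of Fe-NTA directly against 1 week, which also tests whether the responses at the times differ. The lowest genes at 3 weeks relative to 1 week included Dhrs7l1 (-5.58 ± 0.33), Slco1a1 (-4.15 ± 0.59), Hnmt (-3.23 ± 0.20), Slc7a12 (-3.08 ± 0.28) and the aldo-keto reductase Akr1c13 (-2.96 ± 0.20). Higher at 3 weeks were, among others, the siderophore-binding Lcn2 (2.48 ± 0.47), complement component C3 (2.25 ± 0.16), the protease inhibitor A2m (2.34 ± 0.37) and the chemokine Ccl20 (2.12 ± 0.47). The endotoxin co-receptor Cd14 (2.23 ± 0.31) and the mannose receptor Mrc1 (2.08 ± 0.28) were higher too. Cell cycle genes were lower at 3 weeks than at 1 week, such as Top2a (-1.09 ± 0.20). Havcr1 did not pass, at 0.74 ± 0.26, adjusted p = 0.137 in limma. Of the genes named here, Lcn2 had a group mean signal below the added constant of 5. The constant makes the printed size of its log2 difference smaller, and the value remains an estimate with the error given. In all, 389 probe sets were higher and 531 lower at 3 weeks.

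Of 38 cell cycle genes 8 were lower and 30 did not pass (26 were lower adjusted over the list alone), such as Hmmr (-1.53 ± 0.27) and Melk (-1.35 ± 0.16). Of 31 proximal tubule markers 14 were lower and 17 did not pass (19 were lower adjusted over the list alone), with Slc22a6 (-1.90 ± 0.23) and the inositol oxygenase Miox (-1.56 ± 0.19). In the amino acid and xenobiotic list 16 were lower and 14 did not pass (24 were lower adjusted over the list alone), including Nat8 (-2.06 ± 0.15) and the monooxygenase Fmo1 (-1.83 ± 0.22). In the fatty acid oxidation list 6 were lower and 18 did not pass (12 were lower adjusted over the list alone), with Ehhadh (-1.93 ± 0.19). In the oxidative phosphorylation list 1 was lower and 37 did not pass (none passed adjusted over the list alone), the complex II subunit Sdhd (-0.50 ± 0.11). Camera gave adjusted p = 2.6e-14 for the cell cycle list, 1.2e-14 for proximal tubule, 1.7e-16 for amino acid and xenobiotic, 1.7e-08 for fatty acid oxidation and 9.8e-09 for oxidative phosphorylation. An estimated correlation gave adjusted p = 0.292, 0.292, 0.292, 0.165 and 0.433, in that order. In the NRF2 and glutathione list 4 were lower and 23 did not pass, with Gclc (-1.33 ± 0.15), Me1 (-1.24 ± 0.14) and Osgin1 (-1.74 ± 0.16).

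Of 27 macrophage and pan-leukocyte markers 14 were higher and 13 did not pass (22 were higher adjusted over the list alone), with C1qa (1.50 ± 0.20) and C1qb (1.32 ± 0.14). Among 10 T and B cell markers 3 were higher and 7 did not pass (8 were higher adjusted over the list alone), with Cd3g (1.63 ± 0.29) and Cd4 (1.44 ± 0.31). Of 27 tubular injury markers 9 were higher, 1 was lower and 17 did not pass (18 were higher and 1 was lower adjusted over the list alone), with Clu (1.74 ± 0.26), which encodes clusterin, and Cd44 (1.56 ± 0.18). In the stroma and matrix list 5 were higher and 26 did not pass (15 were higher adjusted over the list alone), with Cthrc1 (2.03 ± 0.36) and Loxl1 (1.16 ± 0.18). In the mesenchymal and invasion list 5 were higher and 22 did not pass (10 were higher and 2 were lower adjusted over the list alone), with Cxcr4 (1.97 ± 0.24) and the cadherin Cdh6 (1.22 ± 0.20). In the immediate early list 2 were higher and 14 did not pass (7 were higher adjusted over the list alone), namely Egr2 (2.05 ± 0.21) and Klf6 (1.20 ± 0.24). Epithelial adhesion and keratin genes changed in few members, where 2 were higher and 17 did not pass (6 were higher and 2 were lower adjusted over the list alone), Cldn7 (1.81 ± 0.14) and Tjp1 (0.54 ± 0.11). Of the interferon-responsive genes 1 was higher and 22 did not pass (4 were higher adjusted over the list alone), Bst2 (1.60 ± 0.26). The adjusted p in camera was 1.4e-14 for the macrophage and pan-leukocyte list, 7.8e-06 for T and B cell, 2.1e-09 for tubular injury, 4.9e-08 for stroma and matrix, 0.000181 for mesenchymal and invasion, 0.000453 for immediate early, 0.0225 for epithelial adhesion and 0.00141 for interferon. Their values with an estimated correlation were adjusted p = 0.0680, 0.292, 0.292, 0.292, 0.165, 0.165, 0.433 and 0.455. The epithelial call ended with the tumours added to the fit (adjusted p = 0.414) and without 1-week replicate 2 (0.183) or 3-week replicate 1 (0.0667). The interferon call ended without 1-week replicate 2 (0.344). Ptprz1 was higher at 3 weeks by 1.39 ± 0.31, and Met did not pass, at 0.80 ± 0.22, adjusted p = 0.0851 in limma. Camera did not call the lists of NRF2 (adjusted p = 0.0583), distal nephron (0.627, median 0.02, mean -0.07), endothelial (0.302), podocyte (0.991), adipocyte (0.328), p53 (0.783, median 0.05, mean -0.01), Wnt (0.0606), iron handling (0.315), HIF and glycolysis (0.203) and heat shock (0.354) genes. The means of the heat shock and podocyte lists changed sign under another scaling.

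The count of 920 became 468 and 449 without control replicate 1 or 2. It was 1285 and 1048 without 1-week replicate 1 or 2, and 33 and 219 without 3-week replicate 1 or 2. The balance turned to 710 higher and 338 lower without 1-week replicate 2, and was 8 higher and 25 lower without 3-week replicate 1 and 31 higher and 188 lower without 3-week replicate 2. The count was 529 with dim probe sets kept, 276 without a variance trend, 1961 (993 higher and 968 lower) at an adjusted p under 0.10 and 513 with at least a 2-fold change. With the tumours added to the fit limma called 0, with 1237 at an unadjusted p under 0.05, against 4294 without the tumours and 931 expected by chance. Median scaling gave 1521 probe sets. It moved the median change of all tested probe sets from 0.08 by -0.17, and the share of higher calls from 42.3% to 16.9%.

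**Figure D1:**
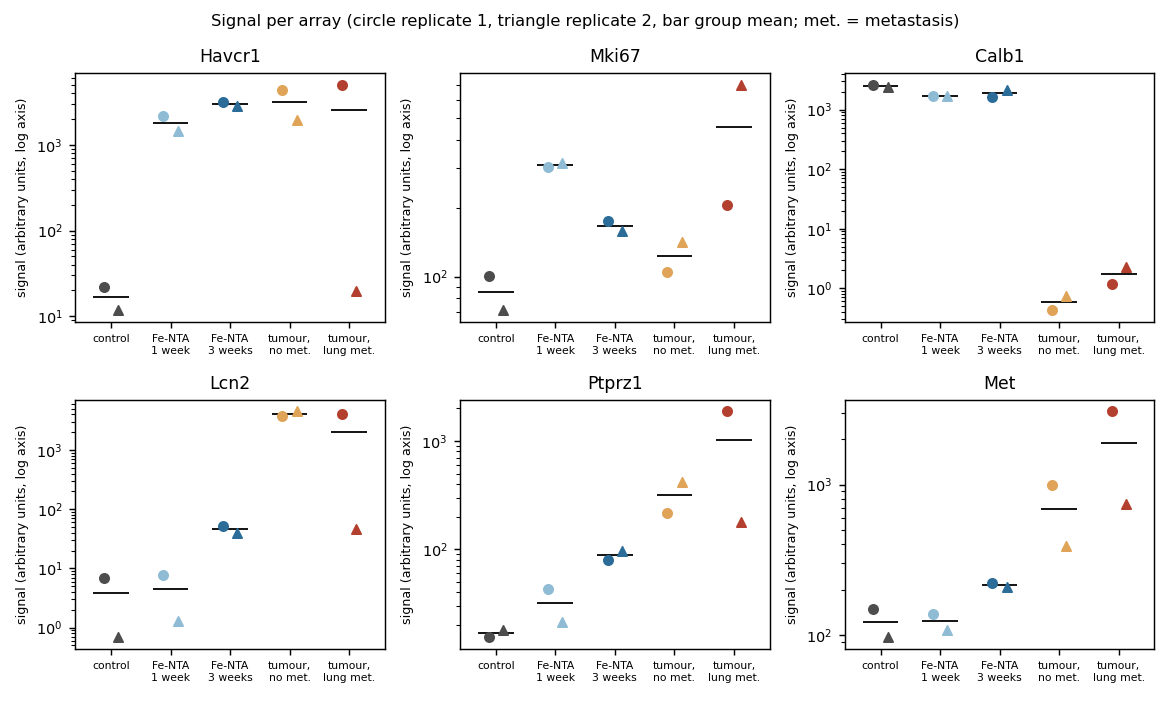
Signal of 6 genes on each of the 10 arrays (log axis, each point 1 array, bars the group means). Havcr1 lay at 21.9 and 11.7 in control kidneys, at 1456 or more in treated kidneys and 3 of the 4 tumours, and at 19.9 in tumour with lung metastasis replicate 2, while Calb1 lay at 1642 or more in kidneys and 2.29 or less in tumours.

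The fourth comparison asked how the tumours differed from control kidney. Markers of nephron segments fell. Calb1, a calcium-binding protein of the distal tubule, had a mean signal of 2519 ± 183 in control, 0.588 ± 0.229 in tumours without and 1.74 ± 0.770 in tumours with lung metastasis (SD, n = 2 each). Its log2 change was -8.68 ± 0.25, adjusted p = 0.000769 in limma. Umod (-8.56 ± 0.91), which encodes uromodulin of the thick ascending limb, and Aqp2 (-8.19 ± 0.25), the water channel of the collecting duct, fell too. So did Slc34a1 (-7.36 ± 0.65), the phosphate transporter of the proximal tubule, and the androgen-regulated tubule gene Kap (-8.51 ± 0.38). The genes that rose most included Lcn2 (7.37 ± 1.64), Gpnmb (5.54 ± 0.63), Epdr1 (5.17 ± 0.29) and the glutathione transferase Mgst2 (4.68 ± 0.46). Cd44 (4.65 ± 0.29), the Fc receptor Fcgr2b (4.57 ± 0.98), Ptprz1 (4.29 ± 0.91) and the TWEAK receptor Tnfrsf12a (3.85 ± 0.24) rose as well. Met rose by 2.96 ± 0.66, adjusted p = 0.0499 in limma. In this comparison Aqp2, Calb1, Kap, Lcn2, Nphs1, Slc34a1, Slc5a2 and Umod had a group mean signal below the added constant of 5. The size and error of their log2 changes depend on this constant, which makes the printed size smaller, and the values remain estimates. Altogether 652 probe sets rose and 1067 fell, at 405 and 690 genes.

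Of 24 distal nephron and collecting duct markers 21 fell and 3 did not pass (1 rose and 22 fell adjusted over the list alone), and Egf (-6.88 ± 0.33) is a further member. Of 31 proximal tubule markers 17 fell and 14 did not pass (26 fell adjusted over the list alone). Examples were the glucose transporter Slc5a2 (-6.21 ± 0.36), the organic anion transporter Slc22a8 (-7.32 ± 0.36) and the ketohexokinase Khk (-4.45 ± 0.27). Of 30 amino acid and xenobiotic metabolism genes 17 fell and 13 did not pass (22 fell adjusted over the list alone), including the decarboxylase Ddc (-5.49 ± 0.28) and Kynu (-4.29 ± 0.34) of tryptophan breakdown. Of 8 podocyte markers 4 fell and 4 did not pass (5 fell adjusted over the list alone), with the nephrin gene Nphs1 (-3.19 ± 0.39) and Podxl (-3.20 ± 0.32). Among 16 endothelial markers 8 fell and 8 did not pass (11 fell adjusted over the list alone), with Emcn (-3.48 ± 0.25), Tek (-3.55 ± 0.27) and Plvap (-3.58 ± 0.32). In the fatty acid oxidation list 11 fell and 13 did not pass (13 fell adjusted over the list alone), with Acsl1 (-2.78 ± 0.23) and Acadm (-2.23 ± 0.26). In the oxidative phosphorylation list 10 fell and 28 did not pass (21 fell adjusted over the list alone), with Sdhb (-1.13 ± 0.17) and Uqcrfs1 (-0.93 ± 0.16). The set test camera gave adjusted p = 5.4e-21 for the distal nephron list, 3.5e-16 for proximal tubule, 4.1e-13 for amino acid and xenobiotic, 0.000836 for podocyte, 2.9e-08 for endothelial, 4.4e-10 for fatty acid oxidation and 4.4e-10 for oxidative phosphorylation. With an estimated correlation these were adjusted p = 0.0390, 0.250, 0.250, 0.203, 0.184, 0.189 and 0.184. A sign of RNA quality moved with these lists. The beta-actin 3' minus 5' log2 difference was 0.26 to 0.42 in the tumours and 0.82 to 1.15 in the kidneys.

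Among 27 tubular injury markers 10 rose, 2 fell and 15 did not pass (11 rose and 2 fell adjusted over the list alone), with Clu (3.59 ± 0.18) higher and the mucosal peptide gene Tff3 (-5.67 ± 0.27) lower. Havcr1 was high in 3 tumours (4408, 1972 and 5077) and at 19.9 in tumour with lung metastasis replicate 2. It did not pass, at 5.59 ± 1.98, adjusted p = 0.138 in limma, and passed at 3.68 (adjusted p = 0.00674) and 7.51 (0.00201) without tumour with lung metastasis replicate 1 or 2, and with all 10 arrays in the fit (0.0481). Of 27 macrophage and pan-leukocyte markers 7 rose and 20 did not pass (8 rose adjusted over the list alone), with Cd14 (3.72 ± 0.47) and C1qb (3.37 ± 0.52). The mean change of this list was 0.77 and 2.73 in replicates 1 and 2 of the tumours without and 1.22 and 2.45 in those with lung metastasis. The interferon list moved with it, at 0.76, 1.77, 1.26 and 1.80. Of 23 interferon-responsive genes 3 rose and 20 did not pass (13 rose adjusted over the list alone), among them Ifi27 (1.55 ± 0.16) and Psmb8 (3.05 ± 0.55). No T and B cell marker passed (2 rose adjusted over the list alone), and the list was higher. Camera gave adjusted p = 0.000160 for the tubular injury list, 1.4e-06 for macrophage and pan-leukocyte, 1.3e-06 for interferon and 0.0135 for T and B cell. They were adjusted p = 0.243, 0.462, 0.250 and 0.523 with an estimated correlation. The T and B cell call ended without tumour without metastasis replicate 2 (adjusted p = 0.0536) or tumour with lung metastasis replicate 2 (0.0672).

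Of 38 cell cycle genes 2 rose and 36 did not pass (17 rose and 1 fell adjusted over the list alone), Mcm4 (1.82 ± 0.39) and the spindle checkpoint gene Mad2l1 (1.96 ± 0.37). The list's mean stood 0.38 and 0.69 log2 above control in the tumours without and 1.15 and 2.33 in the tumours with lung metastasis. In the HIF and glycolysis list 3 rose, 1 fell and 22 did not pass (9 rose and 2 fell adjusted over the list alone), with the lactate dehydrogenase Ldha (1.46 ± 0.25) and the phosphofructokinase Pfkp (2.05 ± 0.26). In the immediate early list 4 rose and 12 did not pass (6 rose adjusted over the list alone), with Atf3 (3.77 ± 0.54) and Egr1 (2.38 ± 0.44). The adjusted p in camera was 1.9e-07 for the cell cycle list, 0.00371 for HIF and glycolysis and 0.00667 for immediate early. An estimated correlation gave adjusted p = 0.462, 0.441 and 0.203, in that order. Single members of other lists rose, such as the stress genes Trib3 (3.26 ± 0.34) and Hspb1 (2.40 ± 0.42), the p53 targets Fas (2.64 ± 0.29) and Phlda3 (2.43 ± 0.41) and the Wnt target Myc (3.05 ± 0.37). In the mesenchymal list Vim (2.96 ± 0.23) and Plaur (3.22 ± 0.52) rose, and in the epithelial list Cldn10 (-4.01 ± 0.68) fell. The iron-related Lcn2 and Hfe (1.82 ± 0.36) rose and Aco1 (-2.31 ± 0.36) fell. Camera did not call the lists of heat shock (adjusted p = 0.870, median -0.07, mean 0.37), p53 (0.0612), Wnt (0.253), mesenchymal and invasion (0.286), epithelial adhesion (0.0655), stroma and matrix (0.179), adipocyte (0.121), NRF2 (0.693, median 0.03, mean -0.37) and iron handling (0.870, median -0.33, mean 0.57) genes. Hmox1 did not pass in limma, at 2.60 ± 0.73, adjusted p = 0.0829, with signals of 86.0 to 1289 in the tumours and 34.4 and 52.6 in control kidneys. The other single genes read in every comparison, Vhl (0.20 ± 0.23), Ctnnb1 (-0.14 ± 0.17), Fyn (-0.01 ± 0.91) and Mtap (1.16 ± 0.56), did not pass. Neither did Hsd3b1 (1.09 ± 1.24), the only adrenal cortex marker tested. Hmox1 passed without tumour with lung metastasis replicate 1 (adjusted p = 0.0115) or 2 (0.0436) and with all 10 arrays in the fit, and Mtap (0.0110) and Hsd3b1 (0.0285) without replicate 2. Of the lung epithelium list 0 of 9 genes were bright enough to be tested.

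The count of 1719 became 38 and 23 without control replicate 1 or 2, with 2 higher and 36 lower and 1 higher and 22 lower. It was 927 and 776 without tumour without metastasis replicate 1 or 2, and 4323 and 3324 without tumour with lung metastasis replicate 1 or 2. It was 4266 (2150 higher and 2116 lower) with all 10 arrays in the fit and 3223 at an adjusted p under 0.10. In simulated data with the spread of these 6 arrays, 1 of 100 probe sets changed by 2 log2 units was recovered. Few probe sets changed there, which makes the adjusted threshold stricter, so this is not the recovery in the real data. The count moved widely when 1 array was left out, so the number of changed genes cannot be read from it.

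The fifth comparison set tumours of rats with lung metastasis against tumours without it, 2 arrays against 2. Limma called 0 probe sets (smallest adjusted p = 0.727), with 1145 at an unadjusted p under 0.05 where 931 would be expected by chance. With all 10 arrays in the fit, which lends the narrower spread of the kidneys to the tumours, it called 308. The 5 genes per direction with the smallest unadjusted p are given as values. Higher values stood at Cav1 (3.94 ± 0.55), the coat protein of caveolae, Hilpda (3.25 ± 0.37), a hypoxia-induced lipid droplet protein, Emb (3.64 ± 0.63), Poglut3 (2.38 ± 0.39) and the transcription factor Etv4 (2.37 ± 0.38). Lower values stood at the sulfotransferase Sult1c2a (-7.14 ± 0.53), the phosphate transporters Slc17a1 (-5.55 ± 0.74) and Slc17a2 (-3.54 ± 0.47), the pyrimidine-degrading Dpys (-3.53 ± 0.48) and the parathyroid hormone receptor Pth1r (-3.65 ± 0.46). Slc17a1 had signals of 625 and 1356 in tumours without metastasis, 30.9 and 5.85 in tumours with it, and 790.1 and 679 in control kidneys. In this comparison Dpys, Prodh, Pth1r and Slc17a2 had a group mean signal below the added constant of 5. The constant makes the printed size of their log2 differences smaller, and the values remain estimates with the error given. Of the 35 genes printed for this comparison, 24 passed with all 10 arrays in the fit and 11 without tumour with lung metastasis replicate 1.

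Camera called 9 of 23 lists with the preset correlation, and no call held with an estimated correlation or in fry of limma. Cell cycle genes had higher values (mean 1.20), with Cdc20 (2.59 ± 0.55), Ttk (2.20 ± 0.48) and Melk (2.15 ± 0.51) as the members with the smallest p. The stroma and matrix list (mean 1.44) was higher, with Col5a1 (2.30 ± 0.55), Mmp2 (1.60 ± 0.40) and Tnc (2.80 ± 0.79). So were the mesenchymal and invasion list (mean 1.36, though 0 rose and 1 fell adjusted over the list alone) and the immediate early list (mean 0.69), with Junb (1.41 ± 0.51) and Ccn1 (1.26 ± 0.50). The set test camera gave adjusted p = 4.2e-13 for the cell cycle list, 5.2e-09 for stroma and matrix, 8.2e-06 for mesenchymal and invasion and 0.00124 for immediate early. Their values with an estimated correlation were adjusted p = 0.606, 0.535, 0.583 and 0.583. Against the mean of the tumours without metastasis, the cell cycle list stood at 0.61 in replicate 1 and 1.79 in replicate 2 of the tumours with it. The matrix list stood at 1.24 and 1.63, the mesenchymal list at 0.73 and 1.99 and the immediate early list at 0.51 and 0.86.

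Lower lists were the proximal tubule markers (mean -2.46, 3 fell adjusted over the list alone), with Slc4a4 (-4.10 ± 0.72) and Slc7a9 (-4.29 ± 0.85), and the amino acid and xenobiotic list (mean -1.92, 2 fell adjusted over the list alone), with Prodh (-2.66 ± 0.44) and Sult1a1 (-3.01 ± 0.51). The NRF2 and glutathione list (mean -0.68), with Gstm2 (-2.37 ± 0.83) and Abcc3 (-1.75 ± 0.39), and the oxidative phosphorylation list (mean -0.16) were lower too. Epithelial adhesion and keratin genes had lower values (mean -1.22), with Krt7 (-2.96 ± 0.57), Krt19 (-4.42 ± 1.56) and Cldn10 (-3.69 ± 0.89). Camera gave adjusted p = 2.0e-12 for the proximal tubule list, 3.0e-10 for amino acid and xenobiotic, 0.0174 for NRF2, 0.0229 for oxidative phosphorylation and 0.0394 for epithelial adhesion. With an estimated correlation these were adjusted p = 0.583, 0.583, 0.606, 0.583 and 0.789. The NRF2 call ended without tumour without metastasis replicate 2 (adjusted p = 0.147) or tumour with lung metastasis replicate 2 (0.465). The oxidative phosphorylation call ended without tumour with lung metastasis replicate 1 (0.118) or 2 (0.149) or tumour without metastasis replicate 2 (0.0939). The epithelial call ended with all 10 arrays in the fit (adjusted p = 0.0685) or with dim probe sets kept (0.0526). It also ended without tumour without metastasis replicate 1 (mean -0.63) and without tumour with lung metastasis replicate 2, where the mean turned to 0.54. Against the tumours without metastasis, replicates 1 and 2 stood at -1.15 and -3.78 in the proximal tubule list and -1.03 and -2.81 in the amino acid and xenobiotic list. They stood at -0.11 and -1.24 in the NRF2 list, -0.11 and -0.21 in the oxidative phosphorylation list and 0.54 and -2.97 in the epithelial list, which changed sign. Replicate 2 lay farthest from the control kidneys, with 6967 probe sets more than 1 log2 unit away against 4493 to 5404 in the other 3 tumours.

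In the HIF list, not called, Slc2a1 (1.98 ± 0.45) and Pdk1 (1.94 ± 0.43) had higher values, as had Oas1a (1.98 ± 0.43) and Mx2 (1.81 ± 0.45) in the interferon list. Camera did not call the lists of HIF and glycolysis (adjusted p = 0.0769), interferon (0.0700), tubular injury (0.562, median 0.31, mean -0.32), distal nephron (0.0686), endothelial (0.843, median -0.06, mean 0.02), podocyte (0.843), macrophage and pan-leukocyte (0.775), T and B cell (0.380), adipocyte (0.715), fatty acid oxidation (0.562, median 0.000453, mean -0.30), iron handling (0.774, median 0.06, mean -0.42), p53 (0.281), Wnt (0.281) and heat shock (0.149) genes. Ptprz1 (0.94 ± 1.14), Met (1.28 ± 0.82), Hmox1 (1.99 ± 0.91) and Havcr1 (-3.05 ± 2.47) did not pass. Without tumour with lung metastasis replicate 1 the value of Ptprz1 was -0.73, and without replicate 2 that of Havcr1 was 0.78. Without tumour with lung metastasis replicate 1, limma called 310 probe sets, a fit in which the lone tumour is assumed to vary like the other group. In simulated data with this spread and few changed probe sets, limma recovered 0 of 100 probe sets changed by 1 log2 unit and 0 of 100 changed by 2.

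The last comparison set the 4 tumours against the 4 kidneys treated with Fe-NTA for 1 or 3 weeks. The nephron genes Umod (-8.24 ± 0.68), Calb1 (-8.19 ± 0.18) and Aqp2 (-7.80 ± 0.26) were lower in the tumours, with Calb1 at a limma adjusted p of 1.4e-05. Hsd11b2 (-6.87 ± 0.35), which inactivates glucocorticoids in the collecting duct, was lower too. Higher in the tumours were Lcn2 (6.01 ± 1.23), Mgst2 (4.27 ± 0.46), Epdr1 (3.87 ± 0.33), the fatty acid hydroxylase Cyp4v3 (3.41 ± 0.22) and the keratin Krt23 (2.72 ± 0.52). Ptprz1 (2.89 ± 0.70), Cttnbp2 (2.65 ± 0.58), the apoptosis repressor Nol3 (2.64 ± 0.41) and the lactate transporter Slc16a3 (2.62 ± 0.58) were also higher. Met was higher by 2.54 ± 0.49. Havcr1, high in treated kidneys as well, did not pass, at -1.18 ± 1.48, adjusted p = 0.649 in limma, and its value was 0.74 without tumour with lung metastasis replicate 2. Without replicate 1 it passed, at -3.10 (adjusted p = 0.00135). In this comparison Aqp2, Atp6v1g3, Calb1, Hsd11b2, Lcn2, Nphs1, Slc34a1, Slc5a2 and Umod had a group mean signal below the added constant of 5. The size and error of their log2 differences depend on this constant, which makes the printed size smaller, and the values remain estimates. In total 729 probe sets were higher and 1390 lower in the tumours, at 372 and 910 genes.

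Of 24 distal nephron and collecting duct markers 22 were lower and 2 did not pass (1 was higher and 22 were lower adjusted over the list alone), with Atp6v1g3 (-6.00 ± 0.26) of the acid-secreting cells. Of 31 proximal tubule markers 22 were lower and 9 did not pass (25 were lower adjusted over the list alone), with Slc34a1 (-6.70 ± 0.50), Slc5a2 (-5.96 ± 0.29) and Slc22a8 (-5.72 ± 0.30). Of 8 podocyte markers 5 were lower and 3 did not pass (5 were lower adjusted over the list alone), with Nphs1 (-3.11 ± 0.32) and Podxl (-2.80 ± 0.24). Among 16 endothelial markers 10 were lower and 6 did not pass (12 were lower adjusted over the list alone), with Tek (-3.08 ± 0.20), Emcn (-3.07 ± 0.18) and Plvap (-3.26 ± 0.24). Of 31 stroma and matrix genes 11 were lower and 20 did not pass (1 was higher and 18 were lower adjusted over the list alone). Examples were Col6a3 (-3.01 ± 0.38), the pericyte receptor Pdgfrb (-1.80 ± 0.19) and the gelatinase Mmp2 (-1.71 ± 0.22). Relative to control, the matrix list's mean was -0.86 and -1.12 in tumours without and 0.25 and 0.64 in tumours with lung metastasis. It was 0.71 and 0.44 after 1 week and 1.26 and 1.09 after 3 weeks, so tumours with lung metastasis overlapped the 1-week kidneys. In the amino acid and xenobiotic list 15 were lower and 15 did not pass (22 were lower adjusted over the list alone), with Ddc (-3.59 ± 0.29) and Kynu (-3.06 ± 0.27). In the fatty acid oxidation list 8 were lower and 16 did not pass (12 were lower adjusted over the list alone), with Acsl1 (-2.13 ± 0.16). In the oxidative phosphorylation list 10 were lower and 28 did not pass (18 were lower adjusted over the list alone), with Uqcrc1 (-0.98 ± 0.15). The adjusted p in camera was 1.8e-24 for the distal nephron list, 4.7e-15 for proximal tubule, 0.000305 for podocyte, 4.1e-08 for endothelial, 7.5e-06 for stroma and matrix, 2.5e-09 for amino acid and xenobiotic, 6.6e-06 for fatty acid oxidation and 3.4e-07 for oxidative phosphorylation. They were adjusted p = 0.00706, 0.284, 0.190, 0.105, 0.105, 0.298, 0.219 and 0.284 with an estimated correlation. The beta-actin 3' minus 5' difference separated the same arrays, at 0.26 to 0.42 in the tumours and 0.82 to 0.99 in treated kidneys.

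In the HIF and glycolysis list 7 were higher, 1 was lower and 18 did not pass (12 were higher and 1 was lower adjusted over the list alone), with Pfkp (1.55 ± 0.22) and Pdk1 (1.32 ± 0.23) beside Slc16a3 higher and Ndrg1 (-0.83 ± 0.15) lower. Of the interferon-responsive genes 1 was higher and 22 did not pass (1 was higher adjusted over the list alone), Ifi27 (0.88 ± 0.16). Of 27 macrophage and pan-leukocyte markers 4 were higher and 23 did not pass (4 were higher adjusted over the list alone), with Cd14 (2.34 ± 0.35) and C1qb (1.90 ± 0.39). Among 19 epithelial adhesion and keratin genes 4 were lower and 15 did not pass (4 were lower adjusted over the list alone), with Muc1 (-3.61 ± 0.28) and Krt7 (-2.09 ± 0.34). The set test camera gave adjusted p = 2.5e-05 for the HIF and glycolysis list, 0.000120 for interferon, 0.00146 for macrophage and pan-leukocyte and 0.0115 for epithelial adhesion. An estimated correlation gave adjusted p = 0.284, 0.363, 0.747 and 0.683, in that order. The macrophage and epithelial calls ended without tumour without metastasis replicate 2 (adjusted p = 0.343 and 0.0945) or tumour with lung metastasis replicate 2 (0.0657 and 0.709). None of the 38 cell cycle genes passed. Of 27 tubular injury markers 8 were higher, 2 were lower and 17 did not pass, with Cd44 (1.99 ± 0.21) higher and Tff3 (-3.93 ± 0.26) and Plau (-1.22 ± 0.13) lower. The p53 targets Cdkn1a (-1.68 ± 0.21) and Sesn2 (-1.39 ± 0.21), the iron-related Bmp6 (-1.59 ± 0.23) and the NRF2 target Ephx1 (-2.15 ± 0.38) were lower. The transporter Abcc3 (1.15 ± 0.19) and the stress factor Atf4 (1.17 ± 0.23) were higher. Camera did not call the lists of cell cycle (adjusted p = 0.915, median -0.05, mean 0.02), tubular injury (0.122), p53 (0.915), NRF2 (0.481), iron handling (0.915, median -0.42, mean 0.22), heat shock (0.0601), mesenchymal and invasion (0.973, median 0.13, mean -0.06), immediate early (0.915, median 0.02, mean -0.10), Wnt (0.915, median 0.16, mean -0.11), T and B cell (0.480) and adipocyte (0.446) genes. The means of the mesenchymal, immediate early and Wnt lists changed sign under another scaling.

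**Figure D2:**
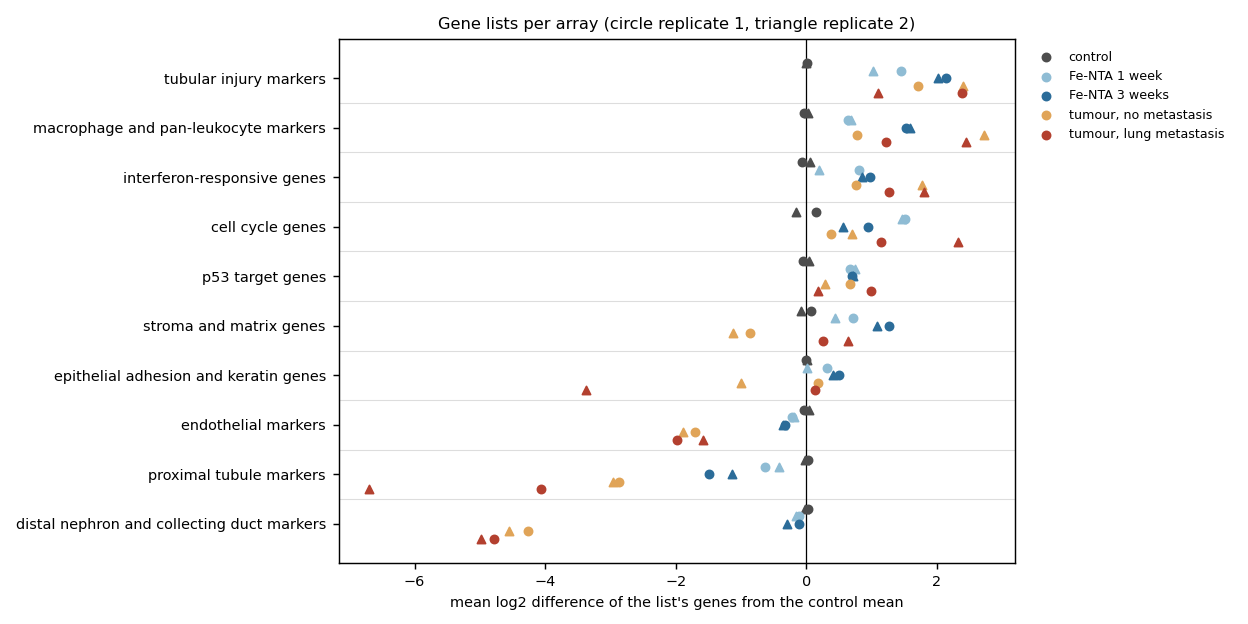
Mean log2 difference from the control mean of the members of 10 gene lists on each of the 10 arrays (points, 1 per array, coloured by group). The cell cycle list stood at 1.51 and 1.47 after 1 week and 0.95 and 0.56 after 3 weeks, and the distal nephron list between -4.98 and -4.26 in the 4 tumours.

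The count of 2119 became 688 and 736 without 1-week replicate 1 or 2, and 615 and 546 without 3-week replicate 1 or 2. The higher among these were 110 and 169, and 74 and 59, and their share was 10.8% to 23.0%. It was 4556 and 3896 without tumour with lung metastasis replicate 1 or 2, 3232 with all 10 arrays in the fit and 3615 at an adjusted p under 0.10. Median scaling moved the median change of all tested probe sets from 0.03 by 0.12. The share of higher calls went from 34.4% to 51.1%.

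Of 23 lists tested per comparison, camera called 16 and 16 after 1 and 3 weeks, 13 between the times, 14 for tumours against control, 9 for lung metastasis and 12 for tumours against treated kidney. With an estimated correlation 2 of these calls held, those of the distal nephron and collecting duct markers in both comparisons of tumours with kidney. Fry of limma, which tests whether a list's members move one way without comparing them to other genes, called in the same direction 9, 14, 10, 10, 0 and 9 of them. Of the genes named above as rising, falling, higher or lower, 8 of 35 after 1 week, 55 of 65 after 3 weeks, 9 of 39 between the times, 7 of 51 for tumours against control and 28 of 47 for tumours against treated kidney passed whichever single array was left out.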

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

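The test of leukocytes as the source of the cell cycle change was chosen after the result was seen, as were the values of Cdkn2a and Cdkn2b. The effects of 3 weeks and of 1 week of Fe-NTA share their controls, and the direct test of their difference passed in limma for 920 probe sets. Lists with higher values at 3 weeks were T and B cell markers (1.10), macrophage and pan-leukocyte markers (0.90), tubular injury markers (0.85), stroma and matrix genes (0.60), immediate early genes (0.53), mesenchymal and invasion genes (0.51), interferon-responsive genes (0.42) and epithelial adhesion and keratin genes (0.29), as mean log2 differences. Lists with lower values were amino acid and xenobiotic metabolism genes (-0.92), proximal tubule markers (-0.78), cell cycle genes (-0.73), fatty acid oxidation genes (-0.44) and oxidative phosphorylation genes (-0.29). None of these list calls held with an estimated correlation (smallest adjusted p = 0.0680), and those of the interferon and epithelial lists ended without 1-week replicate 2 (adjusted p = 0.344 and 0.183). Single genes higher at 3 weeks were Lcn2 (2.48), A2m (2.34), C3 (2.25), Cd14 (2.23), Ccl20 (2.12), Mrc1 (2.08), Egr2 (2.05), Cthrc1 (2.03), Cxcr4 (1.97), Cldn7 (1.81), Clu (1.74), Cd3g (1.63), Bst2 (1.60), Cd44 (1.56), C1qa (1.50), Cd4 (1.44), Ptprz1 (1.39), C1qb (1.32), Cdh6 (1.22), Klf6 (1.20), Loxl1 (1.16) and Tjp1 (0.54), in log2. Genes lower at 3 weeks were Dhrs7l1 (-5.58), Slco1a1 (-4.15), Hnmt (-3.23), Slc7a12 (-3.08), Akr1c13 (-2.96), Nat8 (-2.06), Ehhadh (-1.93), Slc22a6 (-1.90), Fmo1 (-1.83), Osgin1 (-1.74), Miox (-1.56), Hmmr (-1.53), Melk (-1.35), Gclc (-1.33), Me1 (-1.24), Top2a (-1.09) and Sdhd (-0.50).

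Cell cycle genes rose after 1 week and stood lower after 3 weeks, with a mean log2 difference of -0.73. The lower of the 1-week arrays stood 0.52 above the higher of the 3-week arrays, more than the gap within either group (1.51 against 1.47, and 0.95 against 0.56), which argues against 1 array as the cause. The list's median change was -0.85 or lower under both other scalings, which argues against the scaling. The leukocyte list changed by a median of 0.78, so leukocyte transcripts did not fall as a whole. That list does not measure which share of the leukocytes was cycling, so fewer cycling leukocytes cannot be decided from it. The call was lost with an estimated correlation (adjusted p = 0.292). The longer treatment and a changed mix of the remaining cells stay open, both untested.

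Cdkn2a and Cdkn2b, genes of the p16 and p15 cell cycle inhibitors, were too dim on average to be tested, and reached signals of 110.2 and 43.7 in a tumour. Cdkn2a had 3.13 and 0.419 in control, 2.19 and 1.43 after 1 week, 27.6 and 19.7 after 3 weeks, 110.2 and 16.4 in tumours without and 103 and 12.4 in tumours with lung metastasis. With no filter in limma, its log2 change after 3 weeks was 2.10 ± 0.32 (adjusted p = 0.00751). The control signals lie below the added constant of 5, which makes the printed size smaller. In tumours against control it was 2.81 ± 0.94 (adjusted p = 0.160 in limma), which did not pass. Cdkn2b had 0.18 (adjusted p = 0.813) after 3 weeks and 1.16 (0.569) in tumours.

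Of the 35 splits of the 4 tumours and 4 treated kidneys into 4 and 4, 1, the real one, gave 1717 probe sets in limma with 1 mean per side. The highest of the others gave 0. Every other split mixes tumours and kidneys, so their difference enters the spread within each side and calls become unlikely. The count of splits therefore cannot decide on chance.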

How the results depend on the processing

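All alternatives were chosen before the data were examined. Counts of probe sets stayed within 1.5 times of those reported under quantile normalization, both other pseudocounts, a filter of the lowest 60%, robust eBayes, averaging of probe sets per gene and the 4 tumours as 1 group. Median scaling gave 1521 probe sets for 3 weeks against 1 week, where it moves all values of an array by 1 factor. With no filter 1 week gave 212 and 3 weeks against 1 week 529, and without a variance trend 172 and 276; the cause was not tested. With all 10 arrays in the fit, which lends the wider spread of tumours to kidneys and the narrower one of kidneys to tumours, the counts were 0 (limma, 843 at an unadjusted p under 0.05), 102, 0 (limma, 1237 at an unadjusted p under 0.05), 4266, 308 and 3232 in the order of the report. At an adjusted p under 0.10 they were 883 for 1 week, 1961 between the times, 3223 for tumours against control and 3615 against treated kidney, and with at least a 2-fold change 1828 for 3 weeks and 513 between the times, by the wider or narrower threshold.

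Leaving out 1 array gave 24 to 1385 probe sets for 1 week, 1482 to 4610 for 3 weeks, 33 to 1285 between the times, 23 to 4323 for tumours against control, 0 to 310 for metastasis, 546 to 4556 for tumours against treated kidney and 23 to 932 for the overlap. Fewer arrays, and in each case a lone array assumed to vary like the other groups, are part of this. The mean of the oxidative phosphorylation genes at 1 week ranged over -0.177 to 0.0428, with the high end without 1-week replicate 1. For metastasis Ptprz1 ranged over -0.73 to 2.61, with the low end without tumour with lung metastasis replicate 1. Without replicate 2 of these tumours came the high ends of Havcr1 for metastasis (-6.89 to 0.78) and for tumours against treated kidney (-3.10 to 0.74) and of the epithelial adhesion mean for metastasis (-2.97 to 0.54). For tumours against control Hsd3b1 ranged over -0.0628 to 2.24 and Fyn over -0.65 to 0.64, and Fyn was 0.0264 under median scaling and 0.0787 with 4 times the pseudocount. The cause was not tested. No other printed gene changed direction, nor did any other called list in its test. Genes that passed no longer did in 4 cases under quantile normalization, 4 under median scaling, 25 with no filter, 30 without a trend, 127 with all 10 arrays and 365 over all cases of 1 array left out. List calls ended in 78 cases with an estimated correlation and 28 in fry.

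Replicate numbers do not pair the kidneys: the replicate difference correlated across probe sets, which are not independent, at -0.220, 0.0399 and 0.0982 between the kidney groups. A block by these numbers gave 309, 3516 and 830 probe sets for the comparisons among kidneys. Signal near the background limits the rest: genes near the lower end of the signals cannot show a fall.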

Other observations

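The tests of RNA degradation, of 1 array and of the nuclear class as the cause of the metastasis pattern, and the counts along chromosome 4 were chosen after the results were seen, those of 1 array and nuclear class in place of planned bounds in standard errors over list members, which hold no spread between tumours. Mki67, the proliferation marker, had 705 in tumour with lung metastasis replicate 2 and 105, 143 and 208 in the other tumours.

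Nephron markers were lower in all 4 tumours than in control kidney, with mean log2 changes of the distal, proximal, podocyte and endothelial lists of -4.26, -2.87, -2.02 and -1.71 in tumour without metastasis replicate 1, -4.56, -2.96, -1.75 and -1.88 in replicate 2, -4.78, -4.06, -2.16 and -1.98 in tumour with lung metastasis replicate 1 and -4.98, -6.69, -1.52 and -1.58 in replicate 2. The beta-actin 3' minus 5' difference of every tumour lay below that of both controls, with a difference of -0.65 at the closest, which argues against degraded tumour RNA. Distal and endothelial lists differed by at least 4.28 standard errors over members within each tumour. The added constant of 5 caps the fall a dim gene can show, and the lists were not matched for signal. Unequal falls of these 2 lists could therefore arise under 1 common dilution of all kidney cell types. The proximal list changed by -6.69 in tumour with lung metastasis replicate 2, so the constant allows its members such a fall. In the tumours without metastasis it changed by only -2.87 and -2.96 (standard errors over members 0.44 and 0.46), beside -4.26 and -4.56 in the distal list (0.50 and 0.52). This argues against 1 common dilution of proximal and distal segments in those tumours. For the endothelial and podocyte lists it stays open. The labels give the strain of 0 arrays, so strain and tumour cannot be told apart. No biological explanation was tested.

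As lists, cell cycle and matrix genes had higher values in the tumours with lung metastasis, with calls lost at an estimated correlation (adjusted p = 0.606 and 0.535), and no member passed in limma. In the cell cycle list the lower of these tumours stood 0.61 above the mean of the tumours without, against gaps of 1.18 between the tumours with and 0.31 between those without lung metastasis, so 1 array as the cause stays open. In the matrix list the lower stood 1.24 above it, against gaps of 0.39 and 0.26, which argues against 1 array as the cause there. The G3 tumours, both with enlarged nuclei, differed by 1.63 in cell cycle and 1.76 in matrix genes, against 0.31 and -0.26 between G3 and G1 without metastasis, and with 1 array per class and outcome, outcome, nuclear class and tumour-to-tumour differences cannot be told apart.

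Ptprz1, Met, Cttnbp2, Cav1 and Hilpda, named above in a comparison of tumours, lie on chromosome 4, and a gain of the region was a hypothesis. Among all windows of 20 neighbouring genes in a tumour, the neighbours of Met had a median log2 change at percentile 99.98 in tumour with lung metastasis replicate 1 (median 2.48), 98.9 in replicate 2 (0.97), and 99.6 and 86.6 in tumours without metastasis replicates 1 and 2 (0.74 and 0.47). A kidney without tumour, 1-week replicate 1, reached percentile 99.3 with a median of 0.38, and the other treated kidneys 59.2, 88.6 and 85.4, so the percentile alone does not mark a gain. The neighbours of Ptprz1 reached 99.7 in tumour with lung metastasis replicate 1 and 43.6 to 61.5 in the other 3. Of 593 windows on the chromosome, 77 and 89 lay in the genome's highest 2.5% in tumours with lung metastasis replicates 1 and 2, 15 and 6 in those without, and 5 to 14 in treated kidneys. Met itself stood 2.99 and 1.65 log2 above control in replicates 1 and 2 of the tumours without and 4.62 and 2.57 in those with lung metastasis. Ptprz1 stood at 3.36, 4.28, 6.43 and 3.09 in the same order, also where its neighbours did not stand out. Cttnbp2 and Hilpda were above control in every tumour, while Cav1 was at -0.75, -1.79, 2.19 and 3.15. RNA alone was measured here, so a gain of DNA remains a hypothesis that is not tied to the outcome, and shared regulation of neighbours stays open.

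A loss of the region of Cdkn2a and Cdkn2b was tested in the same way. Their neighbours' median change lay at percentile 9.21 at the lowest over the 4 tumours, above the bound of 2.5 set for a loss. That was tumour without metastasis replicate 1, with a median of -0.56 log2 against 0.14 over all windows, and with Cdkn2a itself at 110.2. The median was -0.25 in replicate 2, and 0.55 and -0.06 in tumours with lung metastasis replicates 1 and 2. A percentile among all windows cannot decide whether a fall of this size is a loss, and says nothing on a narrower one.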
